A study of Mus musculus with 6 samples.

How the data were processed

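RNA-seq was available for 6 mouse tumour grafts, 3 labelled WT and 3 labelled AXL KO, and each library was placed in its group by its sample title. Total RNA was purified with Trizol and columns, per the labels' protocols. Base calling with CASAVA 1.8, alignment with TopHat2 2.0.10 to GRCm38, counting with HTSeq 0.5.3 and testing with DESeq2 1.4.5 are named in the submitters' processing notes. Settings of these tools, including the use of strand in counting, are not given in the sources used here. Without a statement on strand, reads of a gene and of an overlapping or antisense gene cannot be told apart.

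The deposited file of each library holds 1 raw count per gene for 39179 gene identifiers, followed by 5 rows that name no gene. Those 5 rows were kept out of library sizes and tests. Alignments that were not unique made up 25.7% to 29.0% of all counted lines, alignments in no annotated gene 4.41% to 6.88%, and ambiguous ones 0.717% to 1.09%. Reads that align to several copies of a gene are therefore missing from the gene counts, and the split of the rest between near-identical copies is uncertain. The authors also deposited a table of their comparison. Its columns per library hold a signal, which equals the deposited count divided by 1 size factor per library for every gene with a count, within a relative deviation of 5.15e-10. It also gives the authors' log2 fold changes with their standard errors and the authors' p-values, raw and adjusted. The deposited log2 fold change has the sign of WT over AXL KO, and it was turned round for the comparison here. This table was described and compared, and it was not retested.

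Counts in genes ranged from 26541009 to 32491807 per library. Replicates of a group differed by more than sampling noise, with a chi-square per gene of 11.7 to 31.3 between libraries of a group and 99.0 to 161 between groups, so all 6 libraries were counted separately. Gene positions came from the GENCODE M21 annotation of GRCm38, which held 37607 of the gene identifiers. Gene symbols came from the deposited table.

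Genes were kept with the edgeR function filterByExpr at its minimum count of 10 and minimum total of 15, which left 14850 of 21716 genes with any count. The 6866 genes removed held at most 0.0456% of the counts of a library. TMM factors lay between 0.980 and 1.02. The groups were compared with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05 and group as the only term. The biological coefficient of variation was 0.117, and the design had 4 residual degrees of freedom. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1 two-sided, so single values were tested in the model over all genes. Standard errors were taken from the size of the log2 fold change and its F statistic. Levels are CPM, counts scaled by library size and TMM factor, as mean ± SD over 3 libraries.

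The lists of genes and of cell type markers, 37 in all, were fixed before the data were examined, as were the tests, the alternatives and the rule for the genes named. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 37 lists, and again with a correlation estimated per list and with fry. Beside each test stand the number of members called over all genes and the number adjusted over the list alone. The rule named the TAM receptors and ligands, the 10 largest increases and the 10 largest decreases among protein-coding or unclassified genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and groups that did not overlap, and up to 4 members of each list with the smallest p. It took 165 genes, of which 142 passed the test, and the text names part of them, with some genes not reported here. A gene named outside the rule is said to be so.

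The steps were tested on simulated data with the means and library sizes of the real genes, in which 200 of 14850 genes were changed between the groups. Of 50 genes each, edgeR recovered 46% at 1.5-fold, 84% at 2-fold, 80% at 3-fold and 96% at 4-fold, and it called 0.0683% of the unchanged genes. The simulation changed few genes and moved no chromosome medians, whereas 37.4% of tested genes were called in the real data. These shares therefore do not measure recovery or false calls in the real fit.

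Calls within 10 Mb of Axl were compared with calls elsewhere by Fisher's exact test, two-sided. Alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean log2 CPM of 2, a replicate block, each library left out in turn, an adjusted p of 0.01, a 2-fold minimum, and windows of 5 and 20 Mb around Axl. Removal of each chromosome's median log2 fold change, and a count without the genes of the interferon and MHC lists, were added after seeing the data, as were comparisons of the genes around Axl with the rest of its chromosome, with autosomes whose median did not move and with chromosome medians removed. The comparison of chromosomes and the lookup of 20 gene families were also chosen after seeing the data.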

Results

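The series holds RNA-seq of mouse mammary tumour grafts grown in FVB mice. The grafted cells came from the MMTV-Neu model, in which the Neu (ErbB2) oncogene is driven in mammary epithelium, and they were either wild type or knockout for Axl, a receptor tyrosine kinase of the TAM family. There were 6 libraries, 3 labelled WT and 3 labelled AXL KO. The comparison asks which transcripts differ between grafts formed with and without AXL in the grafted cells. A graft also contains host cells, so each library holds transcripts of tumour, stroma, vessels and leukocytes together. The WT libraries held 26541009, 29977133 and 28576350 counts in genes, and the AXL KO libraries held 28808499, 32491807 and 30707339. Between 18555 and 19028 genes had at least 1 count in a library. The labels do not say that the 3 grafts of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. They also do not say whether the WT and AXL KO cells came from the same tumour line or isolate, so every difference given below may reflect the line as well as AXL.

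Axl, the targeted gene (ENSMUSG00000002602, GRCm38 chromosome 7, 25757273 to 25788705), was counted at similar levels in both groups. Its counts were 1906, 1761 and 1507 in the libraries labelled WT and 1360, 2396 and 1767 in those labelled AXL KO. Its mean was 60.4 ± 8.95 CPM (library-scaled counts, SD, n = 3) in the WT libraries and 60.1 ± 13.1 CPM (SD, n = 3) in the AXL KO libraries. The log2 fold change was -0.01, with a 95% interval from -0.37 to 0.36 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.978). The labels do not give the part of the gene that was deleted, and the counts cover the whole gene, so Axl neither set the groups apart nor checked the genotype. All directions below are therefore between libraries as labelled. None of the 5 TAM receptors and ligands passed the test, over all genes or adjusted over the list alone (camera adjusted p = 0.955). Gas6, the ligand of the TAM receptors, had a log2 fold change of 0.39 ± 0.17 (SE) and an edgeR adjusted p of 0.105. Without WT replicate 1 this became 0.64, with an adjusted p of 0.00083, and with a replicate block 0.42, with an edgeR adjusted p of 0.0453. The other receptor genes, Tyro3 and Mertk, lay at -0.17 ± 0.09 and -0.22 ± 0.16 (SE), and Pros1, a second ligand, lay at 0.07 ± 0.08 (SE). Without AXL KO replicate 2, Mertk lay at -0.40, with an edgeR adjusted p of 0.048.

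The libraries labelled AXL KO differed from those labelled WT in a large part of the transcriptome. Of 14850 genes tested, 2835 were higher and 2717 lower in the AXL KO libraries at an adjusted p under 0.05 (edgeR), together 37.4% of the tested genes. At least a 2-fold change was reached by 764 of the higher and 716 of the lower genes. The groups did not overlap in 52.1% of tested genes, against 10% by chance with 3 libraries against 3. Without AXL KO replicate 3 the lower genes numbered 1733, and at an adjusted p under 0.01 the counts were 1610 higher and 1464 lower.

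Interferon-inducible genes and single genes of other kinds made up the 10 largest increases among protein-coding or unclassified genes with a mean log2 CPM of at least 2. Dpyd, the first enzyme of pyrimidine breakdown (chromosome 3, 118562129 to 119432924), rose 47.8-fold, from 0.396 ± 0.111 to 19.1 ± 2.82 CPM (SD, n = 3 per group here and below). Odam, a secreted protein first known from enamel-forming cells (chromosome 5, 87885029 to 87894174), rose 40.2-fold, from 10.3 ± 2.41 to 412 ± 152 CPM. Serpini1, the protease inhibitor neuroserpin, rose 30.3-fold. The other 7 of the 10 largest increases were the MHC class I genes H2-Q7 (36.4-fold) and H2-Q6 (32.1-fold), the GTPase genes Iigp1 (31.5-fold) and Tgtp1 (29.3-fold), and Gm4951, F830016B08Rik and I830012O16Rik, with 26.8-, 23.9- and 22-fold increases. H2-Q6, H2-Q7, Tgtp1, Gm4951, F830016B08Rik and I830012O16Rik have close relatives in the genome that can share reads, so the split of their counts between copies is uncertain. All 10 had edgeR adjusted p-values of 8.4e-05 or lower. The rule took only called genes whose groups did not overlap.

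By the same rule, the largest decreases were in Tpsab1, a mast cell tryptase (chromosome 17, 25343245 to 25345562), and Ppp2r2c, a regulatory subunit of protein phosphatase 2A (chromosome 5, 36868513 to 36955078). Tpsab1 fell from 14.9 ± 6.87 to 0.145 ± 0.0599 CPM, 101-fold lower, with 6, 4 and 3 counts in the AXL KO libraries. It has close relatives that can share reads. Ppp2r2c fell from 73.0 ± 26.0 to 1.11 ± 1.13 CPM, 67.6-fold lower, and Ppp2r2b, of the same subunit family, was 9.63-fold lower. Also lower were Lingo3 (25.9-fold), the transcription factor genes Rfx8 (25.8-fold) and Nfe2l3 (15.5-fold), the desmosome gene Pkp1 (20.5-fold), Rbp7, a retinol-binding protein (14.2-fold), and Rspo3, which enhances Wnt signalling (8.88-fold). The edgeR adjusted p-values of the genes named here were 0.00098 or lower.

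Genes induced by interferon rose together in the libraries labelled AXL KO. All 25 tested genes of the type I interferon list rose, with a median log2 fold change of 3.0, or 8.02-fold. The antiviral gene Ifit3 rose 16.3-fold, from 2.88 ± 0.314 to 47.0 ± 6.70 CPM, and the antiviral genes Isg15 and Bst2 rose 8.18- and 9.0-fold. Of 19 tested genes of the interferon-gamma list 18 rose, and 19 when adjusted over the list alone. Their median log2 fold change was 2.71, with Irgm1, Gbp3 and Gbp4 up 6.77-, 11.5- and 8.11-fold and the transcription factor Irf1 up 2.41-fold. All 13 genes of MHC class I presentation rose, with a median of 1.31. B2m, the light chain of every class I molecule, rose 12.3-fold, from 479 ± 128 to 5892 ± 577 CPM. The class I heavy chains H2-K1 and H2-D1 rose 8.92- and 6.98-fold, and the immunoproteasome subunit Psmb9 rose 12-fold. All 9 genes of MHC class II presentation rose, with a median of 0.98, among them H2-Aa (2.31-fold) and Cd74 (1.97-fold). The camera adjusted p-values of the 4 lists were 7.4e-23, 5.29e-16, 6.46e-12 and 4.56e-05, and for each of them the adjusted p was 0.385 with an estimated correlation. For type I interferon, MHC class I and class II the counts adjusted over the list alone were the same as over all genes. The H2 and Gbp genes belong to families whose members can share reads. Markers of T cells, NK cells and dendritic cells rose in the same libraries, as given next.

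Markers of T cells, cytotoxic lymphocytes and dendritic cells were higher in the libraries labelled AXL KO, all at low levels. Of 15 T cell markers 13 rose, with a median log2 fold change of 1.82. Cd3e, a chain of the T cell receptor complex, rose 4.05-fold, from 0.462 ± 0.121 to 1.90 ± 0.428 CPM, and the kinase Lck rose 3.32-fold. All 10 NK and cytotoxic markers rose, with a median of 2.93, among them the granule protease Gzma (8.81-fold), the activating receptor Klrk1 (14.1-fold) and the NK receptor Ncr1 (10.1-fold). Of 10 dendritic cell markers 6 rose, with a median of 1.07, including Flt3 (3.62-fold) and the cross-presenting cell markers Xcr1 (5.48-fold) and Clec9a (3.86-fold). Adjusted over the list alone, the counts of these 3 lists were the same. Their camera adjusted p-values were 5.97e-06, 4.21e-07 and 0.0118, and for each the adjusted p was 0.385 with an estimated correlation. With a filter at a mean log2 CPM of 2 few of these markers were left to test, with 0 T cell, 1 NK and 1 dendritic cell marker called. The medians then were 0.12, 3.58 and 0.46, with camera adjusted p-values of 0.77, 0.147 and 0.331.

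Camera called none of the lists of other leukocyte markers, while fry called that of B cells and that of mast cells, of which Kit alone was tested. Of 16 macrophage markers 1 rose and 2 fell, with a median log2 fold change of 0.01 (camera adjusted p = 0.936). Fcgr1, an Fc receptor, rose 2.16-fold. Of 9 neutrophil markers 2 fell over all genes and 0 adjusted over the list alone (median -0.55, camera adjusted p = 0.481). Of 4 tested B cell markers 1 rose (median 0.50, camera adjusted p = 0.203, fry adjusted p = 0.0124, upwards), which was Igj, the joining chain of secreted antibody, up 6.92-fold. Kit, the receptor of stem cell factor, rose 1.77-fold from 683 ± 27.6 to 1208 ± 77.1 CPM (camera adjusted p = 0.0742 and fry adjusted p = 0.00117, upwards, for the list), while the mast cell tryptase gene Tpsab1, which is not on the list, fell 101-fold. The other mast cell markers were too low to test, with Cpa3, Tpsb2, Mcpt4 and Cma1 at 43, 41, 45 and 36 counts over all 6 libraries. The list result therefore rests on Kit and does not measure mast cells. Without a filter 1 mast cell marker rose and 1 fell, with a median of -0.04. For macrophages, B cells and mast cells the counts adjusted over the list alone were the same as over all genes. A fit without AXL KO replicate 2 had 5 macrophage markers lower. No neutrophil marker was called lower without WT replicate 1 or 3, without AXL KO replicate 1 or 3, or with chromosome medians removed. Without WT replicate 2, and without AXL KO replicate 2, 3 neutrophil markers were. The neutrophil median ranged from -1.55 to -0.19 over the left-out libraries.

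**Figure D1:**
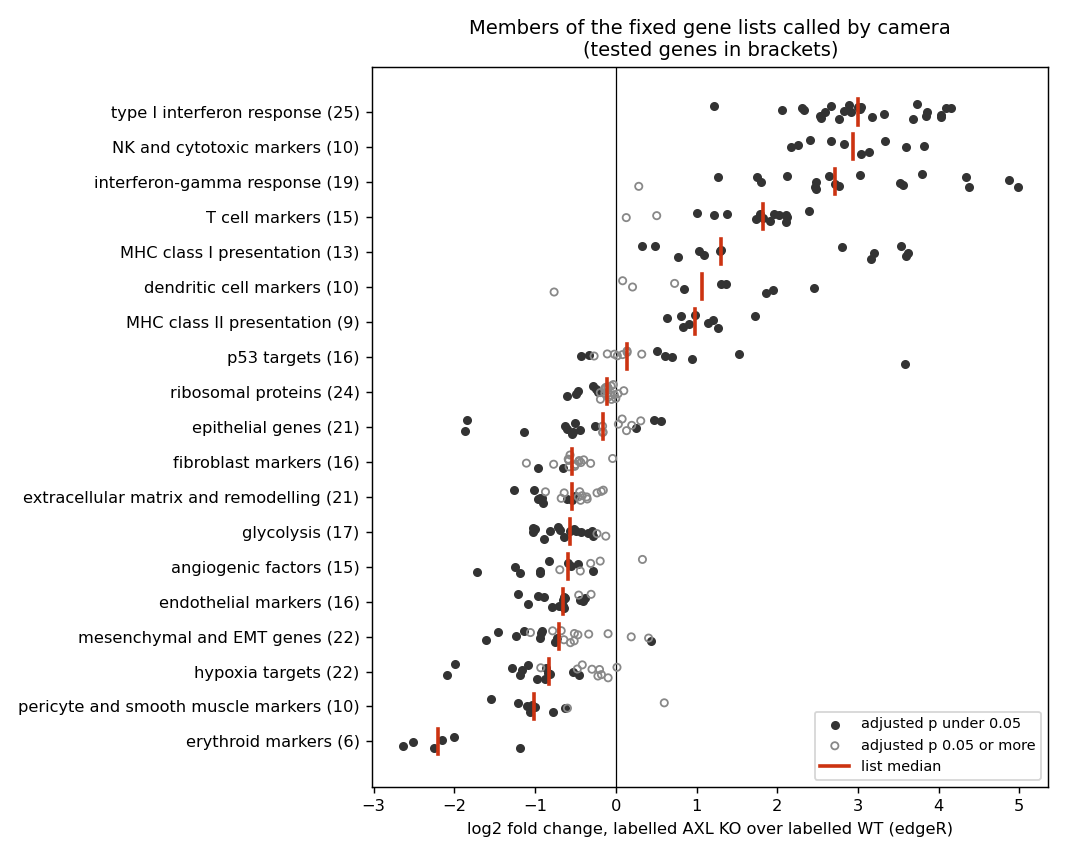
Log2 fold changes (libraries labelled AXL KO over those labelled WT, edgeR) of the tested members of the 19 lists called by camera with its preset correlation, 1 point per gene, filled where the adjusted p was under 0.05, with a red line at each list's median. Type I interferon genes lie around a median of 3.0 and erythroid genes around -2.20, and no list stayed under 0.05 with an estimated correlation.

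Genes of the hypoxia response and of glycolysis were lower in the libraries labelled AXL KO. Of 22 hypoxia targets 13 fell and none rose, with a median log2 fold change of -0.83, and 14 fell when adjusted over the list alone. Adm, the vasodilator adrenomedullin, fell 4.28-fold from 65.8 ± 14.3 to 15.3 ± 7.16 CPM. Ndrg1 fell 3.98-fold, the carbonic anhydrase Car9 fell 2.44-fold, and the prolyl hydroxylase Egln3 fell 1.77-fold. Of 17 glycolysis genes 15 fell, 16 adjusted over the list alone, with a median of -0.56. The phosphofructokinase gene Pfkl fell from 990 ± 39.3 to 494 ± 26.4 CPM, and Gapdh and Pgk1 fell 2.03- and 1.76-fold. Gapdh and Pgk1 have many processed pseudogenes that can share reads. Of 15 angiogenic factors 10 fell, over all genes and adjusted over the list alone, with a median of -0.59, among them Vegfa (2.28-fold), Pgf (3.30-fold) and Pdgfa (1.92-fold). The camera adjusted p-values were 1.31e-05, 7.92e-07 and 0.00145, and with an estimated correlation the adjusted p was 0.519, 0.388 and 0.438. For the hypoxia targets fry gave an adjusted p of 0.0566. Only 8 hypoxia targets and 3 angiogenic factors fell without AXL KO replicate 1, 4 angiogenic factors without AXL KO replicate 3 and 9 glycolysis genes without WT replicate 3, and the median of the angiogenic factors was -0.97 without AXL KO replicate 2, while camera kept the 3 calls.

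Markers of blood vessels and red cells were lower in the same libraries. Of 16 endothelial markers 14 fell, with a median log2 fold change of -0.65, among them the adhesion molecule Pecam1, from 73.2 ± 4.41 to 46.6 ± 6.59 CPM, the transcription factor Sox18 (2.12-fold) and Plvap (1.85-fold). Of 10 pericyte and smooth muscle markers 8 fell, with a median of -1.02, including Rgs5 (2.01-fold), the potassium channel gene Kcnj8 (2.05-fold) and the actin gene Acta2 (2.32-fold). Adjusted over the list alone, 9 pericyte markers fell and 1 rose. All 6 erythroid markers fell, with a median of -2.20. The haemoglobin genes Hba-a1 and Hbb-bs fell 4.77- and 4.02-fold, and each has a near-identical copy, so the split between copies is uncertain. The camera adjusted p-values were 5.12e-06, 0.002 and 3.96e-05, and with an estimated correlation the adjusted p was 0.388, 0.398 and 0.388. For endothelial and erythroid markers the counts adjusted over the list alone were the same. Counts fell to 9 endothelial and 4 pericyte markers without AXL KO replicate 1 and to 4 pericyte markers without AXL KO replicate 3. Without any 1 of the WT libraries 5 pericyte markers fell, and camera kept the endothelial and pericyte calls in all these fits.

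Genes of the extracellular matrix and fibroblast markers were lower in part, and how many were called depended on AXL KO replicate 2. Of 21 matrix and remodelling genes 9 fell, 11 adjusted over the list alone, with a median log2 fold change of -0.55. The basement membrane genes Col4a1, Col4a2 and Lamb1 fell 1.88-, 1.91- and 1.87-fold. Of 16 fibroblast markers 2 fell, 1 adjusted over the list alone, with a median of -0.54, and Pdgfrb, a receptor also carried by pericytes, fell 1.95-fold. The camera adjusted p-values were 2.12e-05 and 0.00936, and with an estimated correlation the adjusted p was 0.473 and 0.678. As many as 17 matrix genes and 9 fibroblast markers fell without AXL KO replicate 2, with medians of -0.85 and -0.83. Adjusted p-values from fry were 0.055 and 0.242, and the fibroblast list lost its camera call without WT replicate 1 (adjusted p = 0.146), where its median was -0.26.

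Mesenchymal genes were lower in part, and so were some epithelial genes. Lists of fibroblast, pericyte and matrix genes were lower in the same libraries, and the counts of the fibroblast and matrix lists also grew without AXL KO replicate 2, as given above. Of 22 mesenchymal and EMT genes 9 fell and 1 rose, with a median log2 fold change of -0.70, and 10 fell when adjusted over the list alone. The membrane protease Mmp14 fell from 109 ± 1.22 to 35.7 ± 12.7 CPM, the EMT transcription factor Snai1 fell 2.76-fold and Sparc fell 1.69-fold, while the surface receptor Cd44 rose 1.35-fold. Of 21 epithelial genes 10 fell and 3 rose, over all genes and adjusted over the list alone, with a median of -0.16. Krt7 and the tight junction gene Cldn4 fell 3.67- and 3.58-fold, Epcam fell 1.44-fold, and the splicing regulator Esrp1 rose 1.47-fold. The camera adjusted p-values were 0.002 and 0.0344, and with an estimated correlation the adjusted p was 0.600 and 0.388. Of the mesenchymal and EMT genes 18 fell without AXL KO replicate 2 (median -1.06), but 3 without AXL KO replicate 1 (median -0.57) and 4 without AXL KO replicate 3 (median -0.44). Both calls ended with the filter at a mean log2 CPM of 2 (adjusted p = 0.0636 and 0.0511), the EMT call with fry (adjusted p = 0.107), and the epithelial call without WT replicate 2 (adjusted p = 0.0965) or AXL KO replicate 2 (adjusted p = 0.058). Of 26 TGF-beta signalling genes 9 fell and 3 rose, with 10 lower when adjusted over the list alone (median -0.05, camera adjusted p = 0.139). Among them Tgfb1 fell 1.58-fold and the target gene Id1 fell 2.80-fold, and fry gave an adjusted p of 0.0305. Tgfb1 (chromosome 7, 25687002 to 25705077) lies close to Axl, and an effect of the altered allele on it was not tested.

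Receptors and ligands of the ErbB family went both ways. Of 13 tested genes 5 rose and 3 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 0.22 (camera adjusted p = 0.481). Erbb4 rose 3.47-fold, from 20.2 ± 5.17 to 70 ± 6.12 CPM, and the ligand gene Egf rose 3.02-fold, while the ligand genes Tgfa and Hbegf fell 1.96- and 2.39-fold. Without WT replicate 1, 3 genes rose and 4 fell. Without WT replicate 3, AXL KO replicate 1 or AXL KO replicate 3, and with a replicate block, 3 rose and 3 fell. Without AXL KO replicate 2, 6 rose and 3 fell. Of 14 ERK pathway outputs 2 rose and 5 fell, with 3 higher when adjusted over the list alone (median -0.01, mean 0.06, camera adjusted p = 0.692). The receptor gene Epha2 rose 6.91-fold and the feedback inhibitor Spry1 fell 2.25-fold. Of 14 immediate early genes 1 rose and 2 fell, over all genes and adjusted over the list alone (median -0.24, camera adjusted p = 0.203). Btg2 rose 1.56-fold and Fos fell 1.89-fold. Without AXL KO replicate 1, 4 genes fell and this list had a camera adjusted p of 0.0181. Its median ranged from -0.381 without AXL KO replicate 1 to -0.0997 without AXL KO replicate 3.

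Of 23 proliferation genes 4 rose, 3 adjusted over the list alone, with a median log2 fold change of 0.05 (camera adjusted p = 0.169). The proliferation marker Mki67 rose 1.37-fold, from 365 ± 41.8 to 501 ± 33.2 CPM, and the cyclin Ccnb2 rose 1.4-fold. Without WT replicate 1 this list had a camera adjusted p of 0.0457, and without WT replicate 2 it had 3 genes higher, 3 lower, a median of -0.02 and a camera adjusted p of 0.996. Of 16 p53 targets 6 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 0.14. The genes that moved furthest were Eda2r, a TNF receptor family member, which rose 11.9-fold, and Trp53inp1, which rose 2.88-fold. Ccng1 rose 1.92-fold. Cdkn1a, the cell cycle inhibitor most used as a p53 readout, lay at 0.02 ± 0.22 (SE) and Mdm2, the p53 ubiquitin ligase, at -0.02 ± 0.07 (SE), both named after their values were seen. The camera adjusted p was 0.0357 for p53 targets, and the adjusted p was 0.388 with an estimated correlation. Without WT replicate 1 it was 0.0684.

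**Figure D2:**
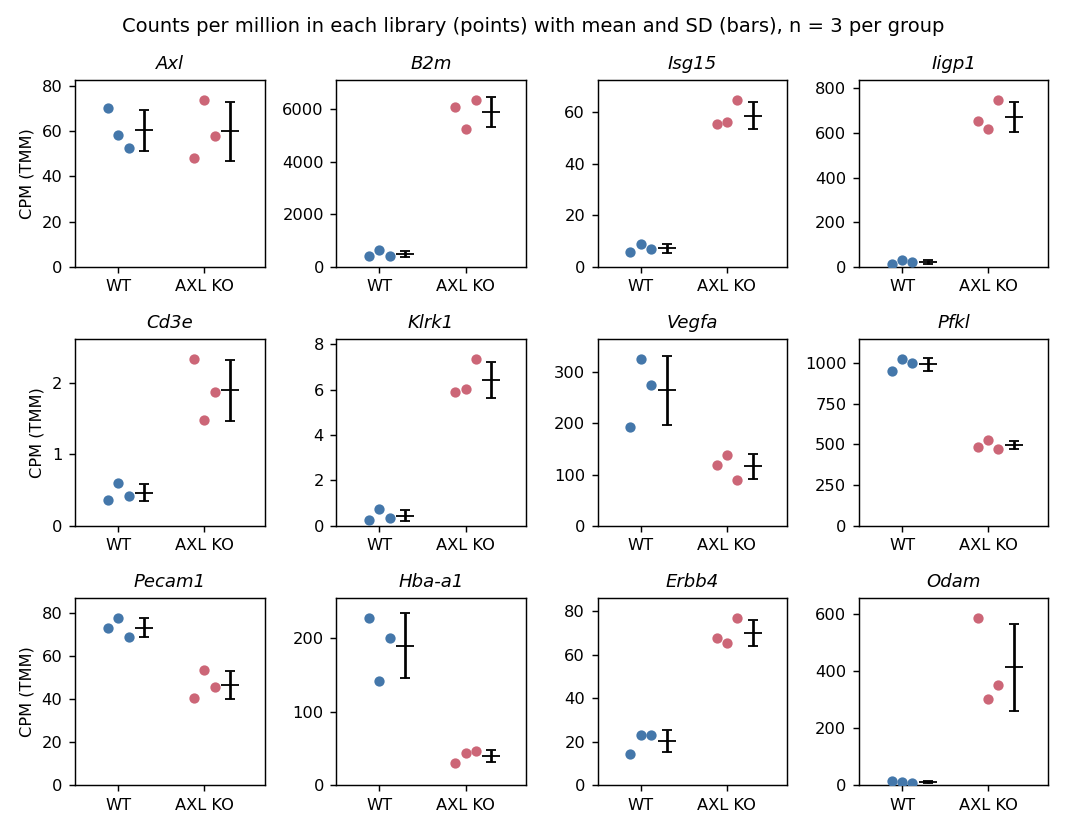
CPM (library-scaled counts, TMM, linear axes from 0) of 12 genes in each of the 3 libraries labelled WT (blue) and the 3 labelled AXL KO (red), with the mean and SD of each group as black bars. Axl overlaps between the groups at means of 60.4 and 60.1 CPM, while the other 11 genes do not overlap, with B2m at 479 and 5892 CPM.

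The remaining lists did not move as groups with camera, apart from ribosomal proteins. Of 24 ribosomal protein genes 6 fell, 4 adjusted over the list alone, with a median log2 fold change of -0.11 (camera adjusted p = 0.00786, adjusted p = 0.678 with an estimated correlation), and without WT replicate 3, 3 fell. Rpl8 fell from 841 ± 46.2 to 551 ± 18.2 CPM, and these genes have many pseudogenes that can share reads. Of 12 mitochondrially encoded mRNAs 4 fell, also adjusted over the list alone (median -0.20, camera adjusted p = 0.0742). Mitochondrial genes took 4.77 ± 0.279% of gene counts in WT and 4.20 ± 0.244% in AXL KO libraries. This list had camera adjusted p-values of 0.0234 without WT replicate 2, 0.0335 without AXL KO replicate 2 and 0.0337 without a filter, and 2 of its genes fell without AXL KO replicate 3. Of 12 milk and luminal secretory genes 3 rose and 2 fell, also adjusted over the list alone (median 0.39, camera adjusted p = 0.154). The iron-binding milk protein Ltf rose 5.86-fold and Wfdc18 rose 2.62-fold, while Lcn2 fell 1.59-fold. Of these genes 5 rose without AXL KO replicate 2. Of 5 tested basal and keratinocyte genes 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.577, downwards). Its median of 0.28 and its mean of -0.46 differed in sign, and fry gave an adjusted p of 0.0105, downwards.

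Of 14 genes of unfolded protein and amino acid stress 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.814). The secretory pathway regulator Xbp1 rose 1.72-fold and Atf4, which drives the amino acid response, fell 1.65-fold. Of 19 cytokine and chemokine genes 3 rose and 4 fell, also adjusted over the list alone (median -0.34, camera adjusted p = 0.692). Their median ranged from -0.41 to -0.15 over the left-out libraries. The T cell attractant Ccl5 rose 2.96-fold, Ccl22 rose 4.0-fold and Cxcl14 fell 1.62-fold. None of 12 adipocyte markers passed the test, over all genes or adjusted over the list alone (median -0.22, camera adjusted p = 0.359). Of 3 tested skeletal muscle markers 1 rose, 2 adjusted over the list alone (median 0.83, camera adjusted p = 0.0877, fry adjusted p = 0.00794, upwards), and the myoglobin gene Mb rose 2.94-fold. Of 7 nerve and Schwann cell markers 2 fell, also adjusted over the list alone (median 0.14, mean -0.05, camera adjusted p = 0.865, downwards), and S100b fell 3.56-fold.

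Across the 37 lists, camera with its preset correlation called 19, of which 8 were higher and 11 lower in the libraries labelled AXL KO. With an estimated correlation camera called 0 lists, and 3 had an unadjusted p under 0.05. The rotation test fry, which does not compare a list with other genes, called 20 lists, 15 of them shared with camera.

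In the authors' deposited table of their own comparison, 5517 genes had an adjusted p under 0.05, of which 2756 were higher and 2761 lower in AXL KO. Of the calls in the authors' deposited table, 94.7% were also called here by edgeR, and all 5227 shared genes had the same direction. At an adjusted p under 0.01 in both, 76.0% of the calls in the authors' deposited table were called here.

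The share of called genes around Axl was below that of all other genes, which include the chromosomes with moved medians given next. Within 10 Mb on either side of Axl, 81 of 290 tested genes passed the test (27.9%), against 37.7% elsewhere. The odds ratio was 0.640, with a 95% interval from 0.488 to 0.833 (Fisher's exact test, two-sided, p = 0.00059). Fisher's test treats genes as independent, while changes were unevenly spread over chromosomes, so its intervals may be too narrow and its p-values too small. In comparisons added after the data were seen, the odds ratio by Fisher's exact test was 0.796 (95% interval 0.584 to 1.08, p = 0.141) against the rest of chromosome 7, where 32.8% of genes passed, and 0.821 (0.624 to 1.07, p = 0.140) against autosomes whose median moved by less than 0.1, where 32.1% passed. With chromosome medians removed it was 0.806 (0.610 to 1.06, Fisher's exact test p = 0.121), so none of these comparisons passed the test. Of the 81 genes 21 were higher and 60 lower in the libraries labelled AXL KO. One of the lower genes was Tgfb1, at 25687002 to 25705077, close to Axl at 25757273 to 25788705.

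Changes were also unevenly spread over the chromosomes, a comparison chosen after the data were examined. On chromosome 4, 394 of 950 tested genes rose and 96 fell, while on chromosome 15, 36 of 568 rose and 243 fell. The median log2 fold change of all tested genes moved by 0.1 or more on 9 of 19 autosomes. It was 0.28 on chromosome 4, 0.20 on chromosome 9, 0.18 on chromosome 11 and 0.14 on chromosome 13, and it was -0.29 on chromosome 15, -0.26 on chromosome 17, -0.22 on chromosome 12, -0.20 on chromosome 10 and -0.13 on chromosome 14.

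**Figure D3:**
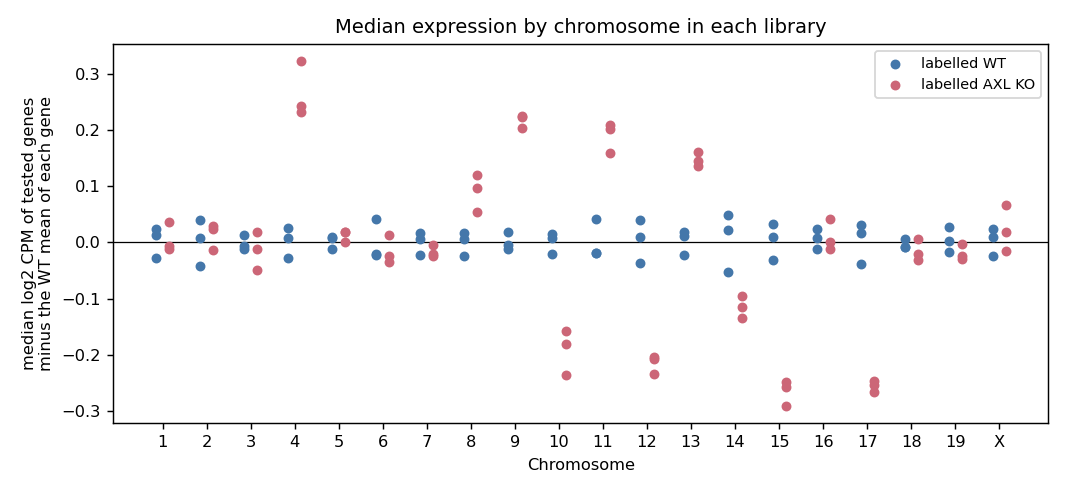
Median over the tested genes of each chromosome of the log2 CPM minus that gene's mean in the WT libraries, 1 point per library, blue for libraries labelled WT and red for libraries labelled AXL KO. The groups do not overlap on 10 of the 19 autosomes, with means over the AXL KO libraries of 0.27 on chromosome 4 and -0.27 on chromosome 15.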

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

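No test was chosen for the value given here. Alignments in no annotated gene, which enter no comparison of genes, took a larger share of the counted lines in the libraries labelled AXL KO, at 6.36 ± 0.712% (SD, n = 3), than in those labelled WT, at 4.87 ± 0.484% (SD, n = 3). The groups did not overlap, which 3 libraries against 3 give by chance in 10% of cases. Ambiguous alignments went the other way, at 0.818 ± 0.0912% in the AXL KO libraries and 1.03 ± 0.0492% in the WT libraries (SD, n = 3).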

How the results depend on the processing

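The removal of chromosome medians and the count without the interferon and MHC lists were chosen after seeing the data. Scaling, tool, filter and left-out libraries gave no shared call of the opposite sign, and no scaling moved the median of all genes by over 0.0202 in size. With DESeq2 93.7% of the calls were shared, and with limma-voom 98.7%. With each library left out in turn, 2000 to 2846 genes were higher and 1733 to 2828 lower, and 66.0% to 88.3% of the calls were shared. The lowest count came without AXL KO replicate 3, and such fits have fewer samples. At an adjusted p under 0.01 the counts were 1610 and 1464, and with a 2-fold minimum 764 and 716, as stricter thresholds must give fewer. Without the genes of the interferon and MHC lists 2770 genes were higher. Around Axl the odds ratio of 0.640 was 0.796 against the rest of its chromosome, 0.821 against autosomes whose median did not move and 0.806 without chromosome medians, all added after seeing the data, and it no longer passed the test. Without chromosome medians 2233 were higher and 2227 lower, and 71.9% of the calls were shared. The stricter filter left 2173 higher and 2292 lower among 11475 genes tested.

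The replicate numbers gave no sign of pairing. The deviations of same-numbered libraries correlated at -0.06, -0.13 and 0.09 across genes, and not every library correlated best with its own number. With 3 libraries per group this check cannot exclude a shared animal, day or batch. A replicate block gave 2458 higher and 2373 lower genes and 19 lists called.

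The Axl log2 fold change stayed without a call in all these fits. Its sign turned without a filter (0.00165) and without chromosome medians (0.0114), and it ranged from -0.184 to 0.131 over the left-out libraries. With an estimated correlation camera called 0 lists in place of 19. At unadjusted p under 0.05 there were 3, and fry called 20. Among lists not called by camera in the main fit, medians that turned sign included those of neutrophil markers (0.326) and of basal and keratinocyte genes (-1.39) with the stricter filter, the latter also without a filter (-0.137), and over left-out libraries TAM genes (-0.135 to 0.116), macrophage markers (-0.172 to 0.15), proliferation (-0.0234 to 0.12), mast cell markers (-0.772 to 0.814), unfolded protein stress (-0.0235 to 0.0432), ERK pathway outputs (-0.0718 to 0.0563) and adipocyte markers (-0.562 to 0.167). The macrophage list, at a median of 0.013, went down with camera and up with fry. The cause of these turns was not tested, but the members tested also changed between these fits. Of the basal genes named by the rule only Sfn, at -1.38 in the main fit, had a mean log2 CPM above 2. The mast cell list held Kit alone in the main fit, while without WT replicate 2 it also had 1 marker lower. Jun, at 0.233, lay at -0.0428 without chromosome medians, since the median of its chromosome 4, 0.275, was subtracted. Over all alternatives, 53 checks of a named gene lost a call and 19 gained one, against 2191 that did not change side. For lists 32 lost and 10 gained a call, against 501. Depth limits the lymphocyte markers, since many lie near 1 CPM and drop out with the stricter filter.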

Other observations

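The tests of the H2 region, of a single exchanged library and of Axl transcripts from other sources were chosen only after the results they bear on had been seen, as were the 20 gene families, the members of them named here, the removal of chromosome medians and the simulation of partly changed chromosomes.

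Gene families were also described, and some share members with the lists above. Gbp genes and Cd274, for example, are on the interferon-gamma list. Since the choice of families followed the fold changes, their p-values are description and no independent support. After the fold changes had been seen 20 families were looked up by gene symbol, and camera called 13 of them with its preset correlation, adjusted over the 20. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, and fry called 15. All 10 guanylate-binding protein genes were higher in the libraries labelled AXL KO, with a median log2 fold change of 3.12 (camera adjusted p = 2.55e-10, adjusted p = 0.251 with an estimated correlation), as were 7 of 8 Schlafen genes, with a median of 2.27 (5.12e-07, adjusted p = 0.221 with an estimated correlation). Of 15 non-classical MHC class I genes 14 were higher and 1, H2-M9, was lower. Their median was 2.85 (camera adjusted p = 5.09e-10, adjusted p = 0.251 with an estimated correlation). Copies in these families can share reads. Of 8 checkpoint and activation genes 5 were higher, with a median of 2.02, among them Cd274, the ligand of PD-1, at 4.33-fold (camera adjusted p = 0.000885, adjusted p = 0.221 with an estimated correlation).

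Part of the Notch and Wnt pathway genes was lower in the same libraries. Of 15 Notch pathway genes 9 fell and 1 rose, with a median of -0.60 (camera adjusted p = 0.0045, adjusted p = 0.265 with an estimated correlation). The endothelial receptor Notch4 fell 2.75-fold and the target gene Nrarp fell 2.50-fold, while Notch1 rose 1.54-fold. Endothelial markers (14 of 16 lower) and pericyte markers (8 of 10 lower), among them Notch3 of the same pathway, fell in these libraries too. Of 17 Wnt pathway genes 6 fell and none rose, with a median of -0.72 (camera adjusted p = 0.0137, adjusted p = 0.369 with an estimated correlation). The transcription factor Lef1 fell 8.50-fold and the ligand Wnt7b fell 4.70-fold. Of 17 glutathione S-transferase genes 8 fell and 1 rose (camera adjusted p = 0.00566, adjusted p = 0.369 with an estimated correlation), and Gstm1 was 3.13-fold lower. Of 27 genes of sterol and fatty acid synthesis 11 rose and 2 fell, with a median of 0.29 (camera adjusted p = 0.0172, adjusted p = 0.569 with an estimated correlation, fry adjusted p = 0.0751). Acaca, which makes malonyl-CoA for fatty acids, rose 2.28-fold, while Fads2 fell 2.44-fold. Camera also called immunity-related GTPases (12 of 13 higher), the Sp100 gene cluster (8 of 8 higher), nucleic acid sensing and JAK-STAT genes (19 higher and 6 lower of 40), S100a genes (6 of 10 lower) and oxidative phosphorylation (19 lower and 1 higher of 88), with an adjusted p of 0.251, 0.243, 0.369, 0.369 and 0.749 with an estimated correlation. For oxidative phosphorylation fry gave an adjusted p of 0.334. Keratins, claudins, tumour suppressors, histone genes, serpins, oncogenes with Erbb2 neighbours and genes with symbols starting with Eph were not called by camera, and of these fry called keratins, claudins, tumour suppressors and the Eph group.

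Interferon and MHC class I genes were higher in the libraries labelled AXL KO. Transcripts brought in by more leukocytes of all kinds do not account for the whole rise. The 16 pan-leukocyte genes had a median log2 fold change of 0.50, with 9 higher and none lower. The type I interferon list lay above them by 2.50 (95% bootstrap interval 2.13 to 3.12). Bootstrap intervals in this paragraph measure spread over genes and not between libraries, and genes changed together (estimated correlation 0.879 in the type I interferon list). The most abundant pan-leukocyte genes were Lcp1, at 419 CPM in WT and 450 CPM in AXL KO libraries, and Laptm5, at 56.4 and 63.2 CPM, neither of them called. Ptprc, Ikzf1 and Cd52 rose 1.86-, 1.91- and 2.34-fold. Which cells these transcripts came from was not tested. T cell and NK markers, at low levels, had higher medians of 1.82 and 2.93, while the macrophage median was 0.01. Strain differences in the H2 genes are argued against only for the 49 list members outside the H2 region, with a median of 2.83 (2.55 to 3.17). For class I genes inside that region, such as H2-K1 and H2-D1, strain differences were not tested. The chromosome-wide shifts are argued against by the type I interferon median, which was 0.993 times its value (0.945 to 1.05) after their removal. It stays open and untested what lies behind the rise. AXL loss, another difference between the grafted cell populations, or interferon made by the lymphocytes whose markers also rose may lie behind it.

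Chromosome-wide shifts between the groups moved the median by 0.1 or more on 9 of 19 autosomes. GC content or gene length bias is argued against, since the SD of the autosome medians kept 0.993 of its value after a fit on both. Whole-chromosome dosage differences between the grafted cell populations predicted one sign along each chromosome, and 57 of 57 windows of 20 Mb had their chromosome's sign (a share of 1), while a simulated change of a single stretch with 50% of each chromosome's genes gave 78.3% on average and 91.2% at most in 1000 draws at the same chromosome medians. The window medians varied in size, from 0.325 to 0.0520 on chromosome 11 and from -0.151 to -0.0509 on chromosome 14. Changes of more than 50% of a chromosome's genes were not simulated, so large partial changes were not told apart from whole-chromosome ones. Gains and losses of chromosomes or of large parts of them in one of the populations remain a hypothesis, and no DNA was analysed here. After removal of the shifts the hypoxia and glycolysis genes together had 1.04 times their median (0.816 to 1.36, an interval over genes and not libraries). The shifts therefore do not account for the lower level of these genes.

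Axl counts were not lower in the libraries labelled AXL KO. A single library exchanged between the groups is argued against, since 6 of 6 libraries correlated best with a library of their own group. Axl transcripts from host cells or from the remaining part of the knockout allele cannot be told apart from an intact gene, since the log2 fold change was -0.00694 (95% interval -0.37 to 0.36) and counts over the whole gene do not show which exons were read. An exchange of the labels of whole groups was not tested.

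DNA of another strain carried along with a knockout allele would raise the share of called genes around Axl. It was not raised, with an odds ratio of 0.640 (95% interval 0.488 to 0.833), 0.522 and 0.659 in windows of 5 and 20 Mb, and 0.796 (0.584 to 1.08) against the rest of the chromosome, a comparison added after the data were seen. These intervals treat genes as independent and may be too narrow. A share over 290 genes cannot show a change in a few of them, so strain DNA with few effects is not excluded. For the number of called genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many as 5552, and the highest of the other splits gave 0. With 10 splits the share cannot go under 0.1. Each other split mixes libraries of both labels, and a difference between the labels then adds to the spread within a side. Its count is therefore no measure of chance.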
